A study of Mus musculus with 18 samples.

How the data were processed

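The series holds 18 samples, which are 3 libraries (RNA, antibody tags and T cell receptor) for each of 6 mice. The T cell receptor libraries were not analysed here. Per the labels, thymocytes of mixed bone marrow chimeras (14 weeks of age) were sorted as CD44 low, CD45.1.2 positive, Vbeta5 and Valpha2 positive cells, and libraries were made with the 10x Genomics 5' v2 protocol, hashtags and TotalSeq-C antibodies. Per the submitters' processing notes, Cell Ranger 8.0.1, Seurat (no version given) and the genome mm10 were used. The authors deposited RNA UMI counts per gene and cell, without normalization, and antibody UMI counts per antibody and cell, also without normalization. The tool that assigned hashtags to cells and the filters on cells, doublets included, are not stated. The labels disagree on 1 host: the OT2 NoSelection host is given as lacking MHC class II in the treatment and as lacking B2m in a comment, and the first was used. B2m and H2-Aa counts come from donor cells and do not check the knockouts of the hosts.

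The deposited files held 1331 cells, 55494 genes and 180 antibody names, of which 127 had a count. A filter of at least 500 genes and at most 10% mitochondrial UMIs removed 0 cells, since the lowest gene number was 506 and the highest mitochondrial share 9.94%. Each cell was tied to 1 mouse by its hashtag. RNA UMIs ran from 525843 to 1867488 per mouse.

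Clusters were made with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes without receptor, ribosomal and mitochondrial genes and Xist, 20 principal components, 15 neighbours, Leiden resolution 1). Marker lists of 18 classes were fixed. A cluster took a class name where at least 3 and at least 60% of the markers reached 10 CPM and 1.5 times the other clusters and 1 stood among the 25 genes highest by fold; it was compared by number where another class had more markers among the 10 highest. No SP name was given to a cluster where most cells were CD4-CD8- by antibody. Mature SP-like named a cluster only where no other class passed. That naming rule was set after the data were seen. The CD4 and CD8A antibody thresholds, from a 2-component mixture, were also set after the data were seen. Shares of cells have exact Clopper-Pearson 95% intervals, differences of shares have Newcombe intervals, and CPM values have exact Poisson intervals; a count of 0 allows up to 3 counts. These cover counting error only.

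Counts were summed over the cells of each mouse and tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, R 4.3.3) with terms for receptor and host, which leaves 2 residual degrees of freedom that hold departures from additivity and mouse differences alike. There were 2 mice per host term and 3 per receptor. The NoSelection hosts lacked B2m for OT1 and MHC class II for OT2, so that term joined 2 host genotypes. Their difference cannot be told apart from the receptor there. It enters the residual and the comparison of OT2 with OT1. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over 9092 genes or 116 antibodies, in 4 comparisons, two-sided. The SE of a log2 fold change was its size divided by the square root of F. Differences between hosts within 1 receptor got no test. The 21 gene lists with 186 genes (preselection DP, TCR-induced early, post-selection, deletion and agonist, CD4 lineage, CD8 lineage, SP maturation and egress, interferon, Treg, CD8aa IEL precursor, p53, cell cycle, heat shock, MHC class I, gamma delta T, myeloid, B cell, NK and ILC, iNKT, erythroid and thymic epithelium) were tested where at least 3 genes passed the filter, which 16 did, with camera from limma 3.58.1 (preset correlation 0.01) and with fry. Of the 186 genes 2 were matched through a synonym. List medians within a receptor used 10 CPM as a pseudocount. Their percentiles came from 10000 random lists, with each gene drawn on its own from genes of like expression. Such percentiles ignore correlation among list genes and the spread between mice, so they are not tests. Some genes stand in more than 1 list, such as Xcl1, Ikzf2 and Tnfrsf18.

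The design, the lists, the markers, the named genes and the alternatives were fixed before the data were examined, except where said otherwise. Named genes were 28 anchor genes; up to 8 higher and 8 lower called genes by fold with a mean of at least 50 CPM and the same direction in both receptors (in 3 hosts for OT2 against OT1), receptor segments left out, or the 6 with the lowest p where fewer than 5 were called; 5 higher and 5 lower ratios within a receptor with at least 50 UMIs and an interval that excludes 2-fold; and 2 to 4 members of each list. From what this rule yields, the genes and antibodies printed with folds were selected after their values were seen, and ICOS, and GITR outside the comparison that called it, are antibodies that the rule does not name.

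Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no filter on low counts, no receptor or host term, equal cells per mouse (108), cells over the 95th percentile of UMIs left out, cycling clusters left out, each mouse left out, other scaling and limma-trend for antibodies, estimated correlation and fry for lists, and other cluster settings for shares. Chosen after the data were seen were the runs without CD4-CD8- cells and with antibody counts per cell capped at the 99th percentile. No doublet caller was used, and the run without cells over the 95th percentile of UMIs stands as the check on doublets. The run without the cell filter removed no cell and gave the same result. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 25 and 70% (PosSelected against NoSelection, 14 unchanged genes called), 22 and 81% (NegSelected against PosSelected, 12), 16 and 80% (NegSelected against NoSelection, 4) and 34 and 86% (OT2 against OT1, 8). A planted list was called by camera in 4 of 4 comparisons, with an estimated correlation in 0 and by fry in 1. The simulation held no departure from additivity and no correlation among genes. It therefore cannot show how camera with the preset correlation behaves on lists whose genes move together. Reads of near-identical gene segments, such as Trbv12-1 and Trbv12-2, can be split wrongly, though in OT1 mice nearly all went to Trbv12-1. The results of some single genes are not reported here.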

Results

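The data were single-cell RNA and surface antibody counts of thymocytes that carried 1 of 2 transgenic T cell receptors, OT1 (restricted by MHC class I) or OT2 (restricted by MHC class II). Bone marrow chimeras were made with 30% OT1 or OT2 marrow and 70% competitor marrow, and thymocytes sorted for low CD44 and for the transgenic receptor chains were profiled 6 weeks later. The hosts were wild type (PosSelected), carried the antigen under an insulin promoter (RIPmOVA, NegSelected), or lacked B2m (for OT1) or MHC class II (for OT2, NoSelection). There were 6 mice, 1 per receptor and host, so that differences between 2 mice had no replicate check. The files held 1331 cells. The OT1 mice gave 306 (NoSelection), 282 (PosSelected) and 204 (NegSelected) cells with 1867488, 1861286 and 1276716 RNA UMIs. The OT2 mice gave 108, 254 and 177 cells with 525843, 805275 and 589450 RNA UMIs in the same order of hosts. The median RNA UMIs per cell were 5135 in OT1 and 2893 in OT2 mice. Antibody UMIs per mouse ran from 422283 (OT2 NoSelection) to 1234798 (OT1 NoSelection). Intervals below are 95% intervals for counting error only.

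The first question was which thymocyte stages each host held. The CD4 SP-like class, marked by Zbtb7b, Cd40lg and Cd4, made up 51.6% of OT2 PosSelected cells (131 of 254). It made up 4.63% (exact Clopper-Pearson interval 1.52 to 10.5%) in the OT2 NoSelection and 7.34% (3.97 to 12.2%) in the OT2 NegSelected mouse, and PosSelected minus NoSelection was 46.9 points (Newcombe interval 38.5 to 53.6). At Leiden resolution 1.5 the OT2 NegSelected share was 16.4%. The name then included clusters of 102 and 64 cells (52.0% and 35.9% CD4+CD8-) that the naming rule does not compare by name. In the OT2 NoSelection mouse the preselection DP-like class, marked by the recombinase genes Rag1 and Rag2, made up 39.8% (30.5 to 49.7%), against 7.87% (4.88 to 11.9%) in PosSelected and 24.3% (18.2 to 31.3%) in NegSelected. Preselection DP-like cells were 2.29%, 1.06% and 1.47% of the OT1 NoSelection, PosSelected and NegSelected mice, and 4.90%, 6.74% and 1.96% at resolution 0.5. In the OT1 mice the gamma delta T-like class, with Sox13, Trdc and the Trgc genes, made up 42.5% (36.9 to 48.2%) in NoSelection, 13.5% (9.72 to 18.0%) in PosSelected and 40.7% (33.9 to 47.8%) in NegSelected. In OT2 mice it made up 21.3%, 5.51% (2.49% without cells over the 95th percentile of UMIs) and 2.82%.

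The signaled intermediate-like class, marked by Itm2a, a gene induced after positive selection, held 30.5% (23.8 to 37.9%) of OT2 NegSelected cells, 8.27% of OT2 PosSelected and 2.78% of OT2 NoSelection cells. In OT1 mice it held 8.17% (NoSelection), 19.5% (PosSelected) and 14.7% (NegSelected). With 10 principal components it held 10.2% of OT2 NegSelected and 6.38% of OT1 PosSelected cells. The name then covered 58 cells, against 188 in the main setting. An unnamed cluster of 119 cells in that setting also had Itm2a as its top gene. The deletion/agonist-like class, marked by Gadd45b, Tnfrsf9, Nr4a1 and Bcl2l11, held 5.88%, 17.7% and 9.31% of the OT1 and 2.78%, 7.87% and 11.9% of the OT2 NoSelection, PosSelected and NegSelected mice. This class held 6 of 7 of its own markers, 5 of them among its top 10 genes. It also held 4 of 5 CD4 SP-like and 4 of 5 Treg-like markers, and 72 of its 131 cells were CD4+CD8- by antibody. The name therefore does not set these cells apart from Treg-like cells. The shares of this class depended on the cluster setting. At resolution 1.5 the class held 0.355% of OT1 PosSelected, 0.394% of OT2 PosSelected and 8.33% of OT2 NoSelection cells. The same shares with 10 principal components were 1.06%, 0.787% and 9.26%. The name covered 46 and 61 cells in these 2 settings, against 131 in the main one, and in part other cells. Cluster 6 passed the markers of CD8 SP-like cells, but 3 markers of CD8aa intraepithelial lymphocyte precursors stood among its top 10 genes, so it is compared by number. It held 19.1% (14.7 to 24.2%) of OT1 PosSelected cells, against 3.59% and 6.37% of OT1 NoSelection and NegSelected cells. Cluster 7, mainly CD4-CD8- cells with Ly6c1, S100a6 and Ahr, held 20.3% of OT1 NoSelection cells, 12.3% of OT1 NegSelected cells and 0 of 254 OT2 PosSelected cells, which allows a share of up to 1.18%. Cluster 7 took no class name, though it held 7 of 8 mature SP-like, 5 of 6 interferon-exposed and 3 of 4 gamma delta T-like markers. The naming rule barred SP names for it, since 94.2% of its cells were CD4-CD8- by antibody. The cycling class held 10.6% of OT1 PosSelected cells and 0 of 254 OT2 PosSelected cells. The interferon-exposed class held 11.4% (7.78 to 16.0%) of OT2 PosSelected cells and at most 1.96% of the cells of any other mouse. That class was 69.8% CD4+CD8- cells. At resolution 0.5 the cluster of that name held 1.97% of OT2 PosSelected and 20.3% of OT1 NoSelection cells. It was 89.7% CD4-CD8- cells and also held 3 of 4 gamma delta T-like markers, so the name then covered mainly other cells. The CD4 SP-like cluster of that setting held 6 of 6 interferon-exposed markers. Cluster 9 passed no marker list and had a median of 1861 RNA UMIs per cell.

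**Figure D1:**
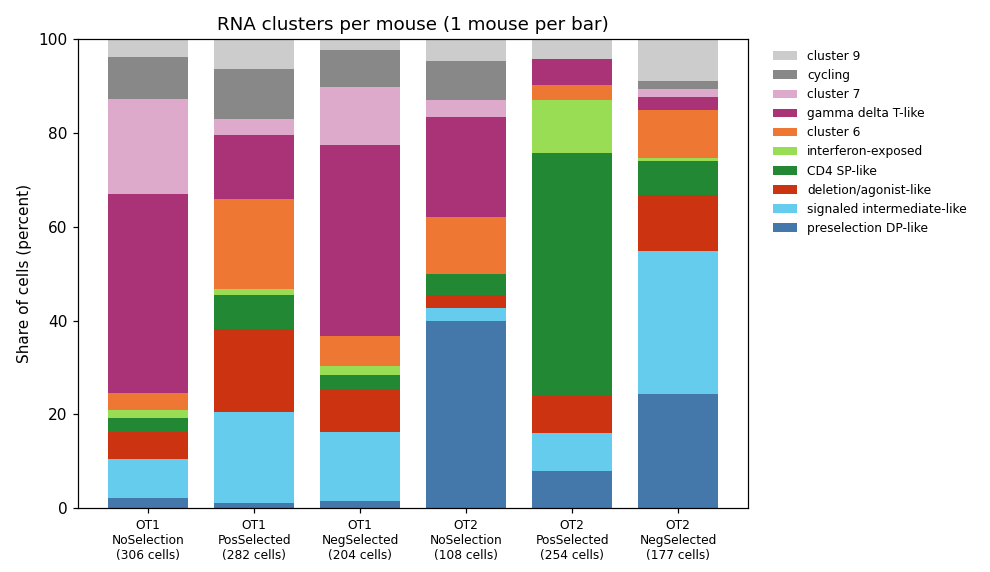
Share of cells (percent, vertical axis) of each RNA cluster in each of the 6 mice, 1 bar per mouse, with gamma delta T-like cells from 2 clusters added up. CD4 SP-like cells make up 51.6% of the OT2 PosSelected bar, and gamma delta T-like cells 42.5% of the OT1 NoSelection bar.

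Surface CD4 and CD8A antibody counts split the cells without RNA clusters. CD4+CD8- cells were 75.6% (69.8 to 80.7%) of OT2 PosSelected cells, against 9.26% in NoSelection and 22.6% in NegSelected. CD4-CD8+ cells were 37.9% (32.3 to 43.9%) of OT1 PosSelected cells, against 12.4% in NoSelection and 11.8% in NegSelected. CD4+CD8+ cells were 40.7% of OT2 NoSelection and 48.6% of OT2 NegSelected cells, against 33 of 254 OT2 PosSelected cells. CD4-CD8- cells were 73.9% of OT1 NoSelection and 67.2% of OT1 NegSelected cells, against 29.8% of OT1 PosSelected cells. The thresholds were set on these cells, and 136 cells lay within 0.5 log2 units of the CD4 threshold and 130 of the CD8A threshold. No class held 20 cells in every mouse, so no gene test within a class was made, and the gene tests below ran on all cells of a mouse added up, with these shares in them.

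**Figure D2:**
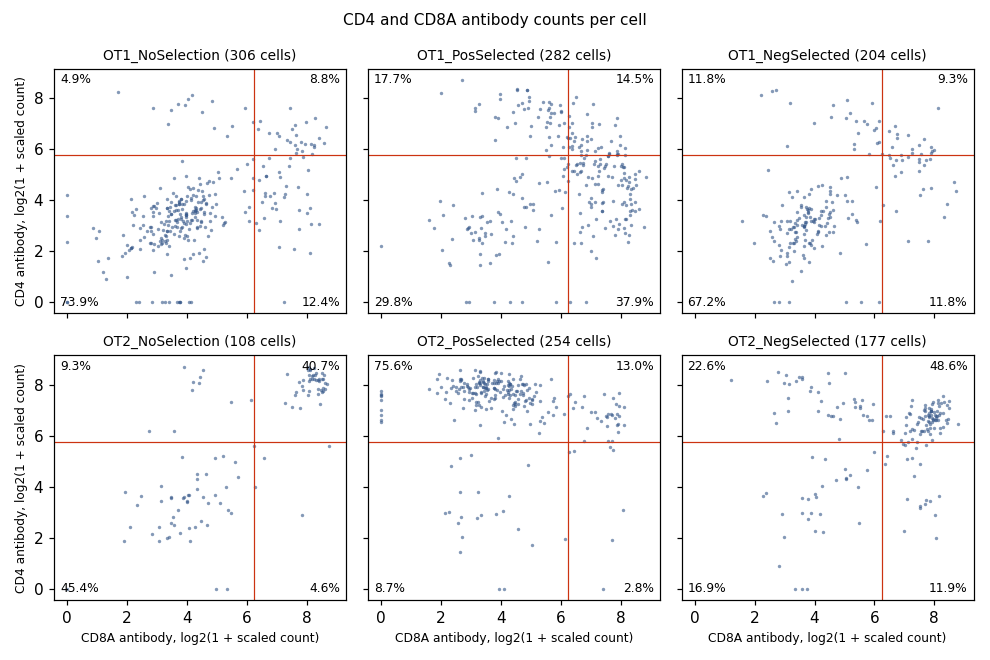
CD4 against CD8A antibody counts per cell (log2 of 1 plus the count scaled to the median total), 1 panel per mouse and 1 point per cell. Red lines are the thresholds and corner numbers the share of cells in each quadrant, 75.6% CD4+CD8- in OT2 PosSelected and 73.9% CD4-CD8- in OT1 NoSelection.

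The comparison of the wild-type host with the non-selecting host asks what changes when the receptor meets its selecting MHC molecule. In PosSelected hosts the lipid phosphatase gene Inpp4b was higher in both receptors, at 380 against 103 CPM in OT1 and 798 against 173 CPM in OT2 (log2 fold change 2.08, SE 0.20, edgeR quasi-likelihood test, adjusted p = 0.0336). Inpp4b was the only gene called of 9092 tested. Genes of the preselection stage were lower together, and genes of CD4 commitment, of maturation and of the interferon response were higher together by camera. Each of these 4 lists had adjusted p = 0.503 with an estimated correlation, and interferon genes had a median log2 ratio of 0.15 in OT1 and 1.85 in OT2. GITR (Tnfrsf18 protein), which marks activated and regulatory T cells, was the 1 antibody called of 116, at 10084 against 2138 CPM of antibody UMIs in OT1 and 4634 against 1220 in OT2 (log2 fold change 2.08, SE 0.19, edgeR adjusted p = 0.0423). The GITR difference rested on few cells: with counts per cell capped at the 99th percentile its log2 fold change was 0.11, not called, and the call was also lost without the OT1 NoSelection (1.93), OT2 NoSelection (2.23) or OT2 NegSelected mouse (2.05).

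By gene list, tested with camera, preselection DP genes fell from NoSelection to PosSelected hosts (8 of 10 tested members below 0, median log2 fold change -1.40, adjusted p = 1.98e-06, and adjusted p = 0.503 with an estimated correlation). Rag1 measured 4.97 against 280 CPM in OT2, Arpp21 93.5 against 250 CPM in OT1 and 86.9 against 500 CPM in OT2, and Dntt, the terminal transferase gene, had a log2 fold change of -1.31 (SE 0.21). Gamma delta T genes fell (4 of 4, median -1.62, adjusted p = 4.34e-05, and adjusted p = 0.503 with an estimated correlation), with Trgc1 at -2.17 (SE 0.34) and Trdc at -1.17 (SE 0.23). These fell with the share of gamma delta T-like cells, which was 29.0 points lower in OT1 and 15.8 points lower in OT2. The 4 list genes are also the markers that name this class, so here and below the list and the share are not independent. SP maturation and egress genes rose (15 of 17, median 0.99, adjusted p = 3.98e-07, and adjusted p = 0.503 with an estimated correlation), with Slfn1 at 3.02 (SE 0.50) and Cd52 at 1.04 (SE 0.18). Interferon response genes rose (12 of 12, median 1.30, adjusted p = 1.98e-06, and adjusted p = 0.503 with an estimated correlation), with Ifi27l2a at 3.24 (SE 0.56), and with 11.4% of interferon-exposed cells in the OT2 PosSelected mouse. The markers of the interferon-exposed class all stand in this list, so that share is no independent check. MHC class I genes rose (9 of 9, median 0.60, adjusted p = 0.000221, and adjusted p = 0.503 with an estimated correlation), with H2-K1 at 1.12 (SE 0.37) and Nlrc5, a transactivator of MHC class I genes, at 1.18 (SE 0.31). The median log2 ratio of the MHC class I list was 1.01 in OT2 and 0.07 in OT1, the 100th and 55.9th percentile of 10000 random lists matched on expression. These percentiles ignore gene correlation and mouse spread and are not a test. CD4 lineage genes rose (3 of 4, median 1.63, adjusted p = 0.0136, and adjusted p = 0.503 with an estimated correlation), with Zbtb7b, the CD4 lineage regulator, at 2.43 (SE 0.56) and Cd40lg at 2.32 (SE 0.45).

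Post-selection genes rose (9 of 11, median 0.32, adjusted p = 0.0089, and adjusted p = 0.503 with an estimated correlation), with Cd2 at 1.70 (SE 0.32), Itm2a at 1.69 (SE 0.41) and the interleukin 7 receptor gene Il7r at 1.00 (SE 0.25). TCR-induced early genes rose (11 of 14, median 0.37, adjusted p = 0.0182, and adjusted p = 0.503 with an estimated correlation), with Cd5, a gauge of receptor signal, at 0.97 (SE 0.34) and Irf4 at 1.95 (SE 0.66). Cell cycle genes fell (14 of 14, median -0.80, adjusted p = 2.60e-05, and adjusted p = 0.559 with an estimated correlation), though in OT1 the list's median log2 ratio was 0.25 and in OT2 -2.24, with Mcm6 at 205 against 198 CPM in OT1 and 37.3 against 274 CPM in OT2. Without the OT2 PosSelected mouse the calls of the interferon (adjusted p = 0.110), MHC class I (0.134), post-selection (0.0666), TCR-induced (0.0958) and cell cycle lists (0.860) were lost. Those of the TCR-induced (0.210), post-selection (0.0947) and cell cycle lists (0.811) were lost without the OT2 NoSelection mouse. The CD4 lineage call was lost without the OT1 NoSelection mouse (0.121), and the TCR-induced call without the OT1 PosSelected (0.0646) or OT2 NegSelected mouse (0.0552). In OT1 and OT2 the median log2 ratio was -0.55 and -1.70 for preselection DP, 0.18 and 1.28 for SP maturation and 0.45 and 1.38 for CD4 lineage genes. It was 0.12 and 0.73 for post-selection and 0.10 and 0.67 for TCR-induced genes. CD8 lineage genes had a camera adjusted p of 0.451, with a median of 0.56 and a camera direction of down; in OT1 their median log2 ratio was 0.51 and in OT2 -0.62. Deletion and agonist genes (median -0.01, adjusted p = 0.388), Treg genes (-0.11, 0.622), CD8aa IEL precursor genes (-0.41, 0.329), p53 genes (median -0.07, mean 0.01, 0.955), heat shock genes (-0.34, 0.317) and myeloid genes (median 0.03, camera direction down, 0.961) were not called. Adjusted over the list alone, 7 preselection DP, 4 gamma delta T, 8 SP maturation, 2 interferon, 1 MHC class I, 4 CD4 lineage and 6 post-selection genes passed, and 0 TCR-induced and 0 cell cycle genes, against 0 of any list over all genes tested by edgeR.

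Other genes with the lowest p were not called: Tesc (2.41, SE 0.32), the creatine kinase gene Ckb (1.86, SE 0.25), Fkbp5, a glucocorticoid-induced gene (-1.49, SE 0.22), and Coro2a (-2.32, SE 0.35) each had an edgeR adjusted p of 0.123. The checkpoint receptor gene Pdcd1 measured 87.6 against 149 CPM in OT1 and 36.0 against 243 CPM in OT2 (log2 fold change -1.62, SE 0.43, edgeR adjusted p = 0.332). Of the 27 anchor genes tested, 10 were higher in both receptors, 10 were lower in both and none was called. Within OT1, without a test, Cd74 measured 51.0 against 5.89 CPM and S100a6 21.5 against 211 CPM. Within OT2, Slfn1 measured 338 against 13.3 CPM and the cycling genes Top2a and Rrm2 measured 3.73 against 167 and 1.24 against 143 CPM. CD5 antibody CPM was 1.58 times as high in OT1 and 3.12 times as high in OT2 (log2 fold change 1.13, SE 0.36, edgeR adjusted p = 0.375), and ICOS antibody had a log2 fold change of 0.93 (SE 0.18, edgeR adjusted p = 0.375). The count of 1 gene compared with 664 genes at an unadjusted p under 0.05, 35 genes by DESeq2 and 11 by limma-voom. It was 248, 162 and 0 without the OT1 NoSelection, PosSelected and NegSelected mouse and 28, 75 and 0 without the OT2 mouse of the same hosts, and Inpp4b was not called without either NegSelected mouse (log2 fold change 2.09 in each run).

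**Figure D3:**
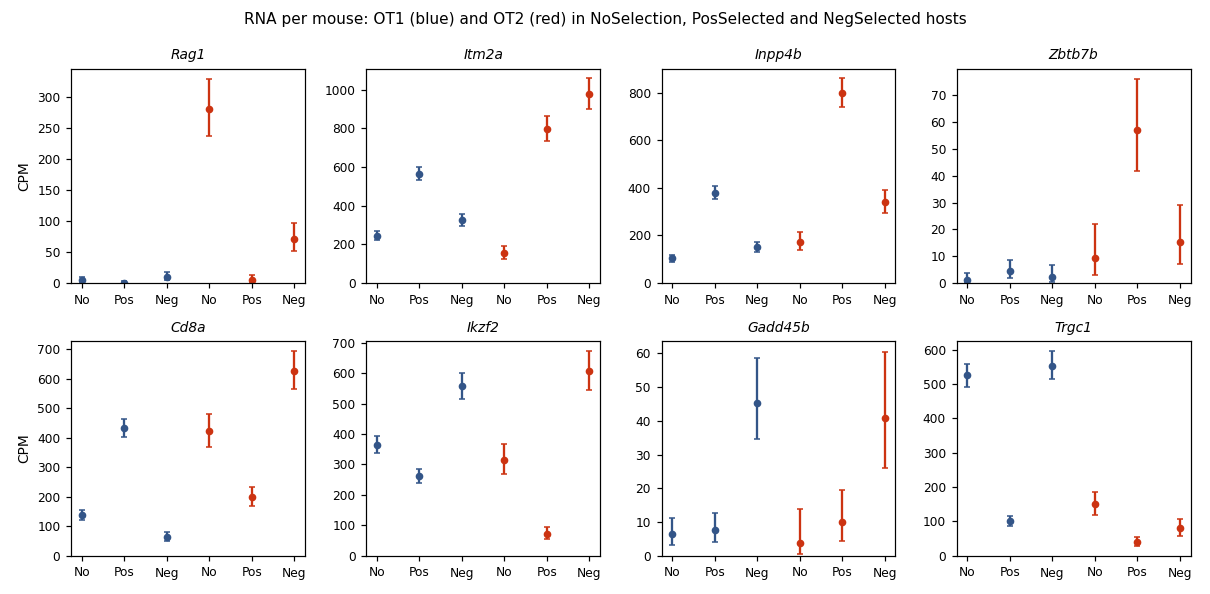
CPM (vertical axis from 0) of 8 genes in the 6 mice, OT1 in blue and OT2 in red, with exact Poisson 95% intervals. Inpp4b is higher in PosSelected than NoSelection hosts in both receptors, and Cd8a goes from 433 to 65.0 CPM in OT1 and from 200 to 628 CPM in OT2 between PosSelected and NegSelected hosts.

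The comparison of antigen-bearing with wild-type hosts asks how thymocytes respond when their antigen is present in the thymus. Deletion and agonist genes rose as a list in NegSelected hosts (14 of 14 tested members above 0, median log2 fold change 1.40, camera adjusted p = 3.19e-15, and adjusted p = 0.491 with an estimated correlation). Gadd45b, a stress and NF-kB target, measured 45.4 against 7.52 CPM in OT1 and 40.7 against 9.93 CPM in OT2. Ikzf2, which encodes Helios, measured 557 against 261 CPM in OT1 and 607 against 73.3 CPM in OT2. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, measured 35.2 against 9.67 CPM in OT1 and 151 against 11.2 CPM in OT2. The share of the deletion/agonist-like class went the other way in OT1, with NegSelected minus PosSelected at -8.42 points (-14.3 to -2.18), against 3.99 points (-1.63 to 10.2) in OT2. The OT1 direction turned with the cluster setting: NegSelected and PosSelected shares were 6.37% and 0.355% at resolution 1.5 and 7.84% and 1.06% with 10 principal components. The name covered 46 and 61 cells in these settings, against 131 in the main one. Their top gene was Ccl5 and not Gadd45b, so these shares are not of the same cells.

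No single gene was called of 9092 by edgeR, with 418 at an unadjusted p under 0.05, 5 by DESeq2 and 0 by limma-voom. Within the deletion and agonist list 11 genes passed adjusted over the list alone, against 0 over all genes tested. Its members with the lowest p were Xcl1 (log2 fold change 5.07, SE 0.64, and in OT2 a ratio of 95.6 with the counting interval 16.6 to 3830), Gadd45b (2.31, SE 0.39), Tnfrsf9 (2.64, SE 0.51) and the orphan nuclear receptor gene Nr4a3 (2.10, SE 0.42). The list also held Ikzf2 (1.86, SE 0.39), Nr4a1 (1.65, SE 0.40), Pdcd1 (1.15, SE 0.42) and the proapoptotic gene Bcl2l11 (0.75, SE 0.25). Treg genes rose (4 of 5, median 0.91, camera adjusted p = 0.00735, and adjusted p = 0.491 with an estimated correlation), with Ikzf2, Tnfrsf18 (0.91, SE 0.23) and Il2ra (1.75, SE 0.58), of which Ikzf2 and Tnfrsf18 also stand in the deletion list. Preselection DP genes rose (7 of 10, median 0.79, adjusted p = 0.000324, and adjusted p = 0.491 with an estimated correlation), with Arpp21 (1.31, SE 0.26), Rag1 (3.95, SE 0.88) and Dntt (0.85, SE 0.21). Gamma delta T genes rose (4 of 4, median 1.18, adjusted p = 0.00214, and adjusted p = 0.491 with an estimated correlation), with Trgc1 (1.89, SE 0.34) and Trdc (0.80, SE 0.22). CD8aa IEL precursor genes rose (4 of 5, median 0.32, adjusted p = 0.00801, and adjusted p = 0.491 with an estimated correlation), in the fit over both receptors mainly through the chemokine gene Xcl1. Within OT2 the median log2 ratio of this list was 1.53, with 5 of 5 members above 0. Within OT1 it was 0.22, with 3 of 5 above 0. The share of gamma delta T-like cells was 27.2 points higher in OT1 NegSelected than OT1 PosSelected cells and 5.51% against 2.82% in OT2 PosSelected and NegSelected cells. SP maturation and egress genes fell (14 of 17 below 0, median -0.56, adjusted p = 0.000324, and adjusted p = 0.491 with an estimated correlation), with Slfn1 (-2.56, SE 0.48) and Cd52 (-0.93, SE 0.18). CD4 lineage genes fell (3 of 4, median -0.79, adjusted p = 0.0379, and adjusted p = 0.491 with an estimated correlation), with Zbtb7b (-1.67, SE 0.52).

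MHC class I genes fell (9 of 9, median -0.47, adjusted p = 0.00348, and adjusted p = 0.506 with an estimated correlation), with the immunoproteasome gene Psmb9 (-0.53, SE 0.24). Interferon response genes fell (10 of 12, median -0.58, adjusted p = 0.00491, and adjusted p = 0.580 with an estimated correlation), with Ifi27l2a (-1.54, SE 0.50). Within OT1 their median log2 ratio was 0.39 and within OT2 -1.59, the 100th and 0th percentile of 10000 random lists matched on expression. With 1 mouse each and genes drawn independently, these percentiles are not a test. In OT1 and OT2 the median was 0.32 and 1.26 for preselection DP, -0.19 and -0.85 for SP maturation, -0.10 and -0.90 for CD4 lineage and -0.06 and -0.75 for MHC class I genes. Without the OT2 PosSelected mouse camera called the interferon list up (adjusted p = 0.0295). In that run the calls of the preselection DP (0.511), SP maturation (0.532), CD4 lineage (0.431), IEL precursor (0.436) and MHC class I lists (0.927) were lost. Without the OT2 NegSelected mouse those of the interferon (0.676, direction turned), CD4 lineage (0.393), IEL precursor (0.206) and MHC class I lists (0.204) were lost. The CD4 lineage call was also lost without the OT1 (0.0688) or OT2 NoSelection mouse (0.0720), and the gamma delta T call without the OT1 PosSelected (0.109) or OT1 NegSelected mouse (0.257). TCR-induced early genes (median 0.14, adjusted p = 0.106), post-selection genes (median -0.13, mean 0.02, adjusted p = 0.761), CD8 lineage genes (median 0.07, mean -0.05, camera direction up, adjusted p = 0.662), p53 genes (0.15, 0.602), cell cycle genes (median -0.07, camera direction up, 0.353), heat shock genes (0.05, 0.591) and myeloid genes (0.41, 0.0933) were not called. Cell cycle genes went opposite ways in the receptors, with a median log2 ratio of -0.45 in OT1 (1 of 14 above 0) and 0.84 in OT2 (13 of 14). CD8 lineage genes did so too (-0.84 and 0.84).

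Inpp4b (-1.34, SE 0.19), Tesc (-2.10, SE 0.31) and the histone deacetylase gene Hdac9 (1.97, SE 0.29) each had an edgeR adjusted p of 0.261, and Gm11707 (-2.79, SE 0.47) had 0.445. Of the 27 anchor genes, 13 were higher and 6 lower in both receptors. The coreceptor genes went opposite ways: Cd8a measured 65.0 against 433 CPM in OT1 and 628 against 200 CPM in OT2, and Cd8b1 71.3 against 378 CPM in OT1 and 651 against 232 CPM in OT2. Within OT1, without a test, the chemokine gene Ccl5 was 10.5 times as high (359.5 against 34.4 CPM) and Ahr 10.8 times as high (40.7 against 3.76 CPM). Within OT2, Ifit1 measured 13.6 against 143 CPM and Ly6a was 9.88 times lower in NegSelected than PosSelected cells. No antibody was called by edgeR (9 at an unadjusted p under 0.05, and 0 by limma-trend on centred log ratios). The ICOS antibody had the log2 fold change -0.88 (SE 0.18, edgeR adjusted p = 0.505) and GITR -0.38 (SE 0.18, edgeR adjusted p = 0.523), which was 0.71 with counts capped at the 99th percentile. Adjusted over the list alone, 3 Treg, 3 preselection DP, 3 gamma delta T, 1 IEL precursor, 2 SP maturation and 2 CD4 lineage genes passed. The gene count was 30, 40 and 0 without the OT1 NoSelection, PosSelected and NegSelected mouse and 59, 22 and 0 without the OT2 mouse of the same hosts. With CD4-CD8- cells left out 6 genes were called and Trdc had a log2 fold change of -0.22.

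**Figure D4:**
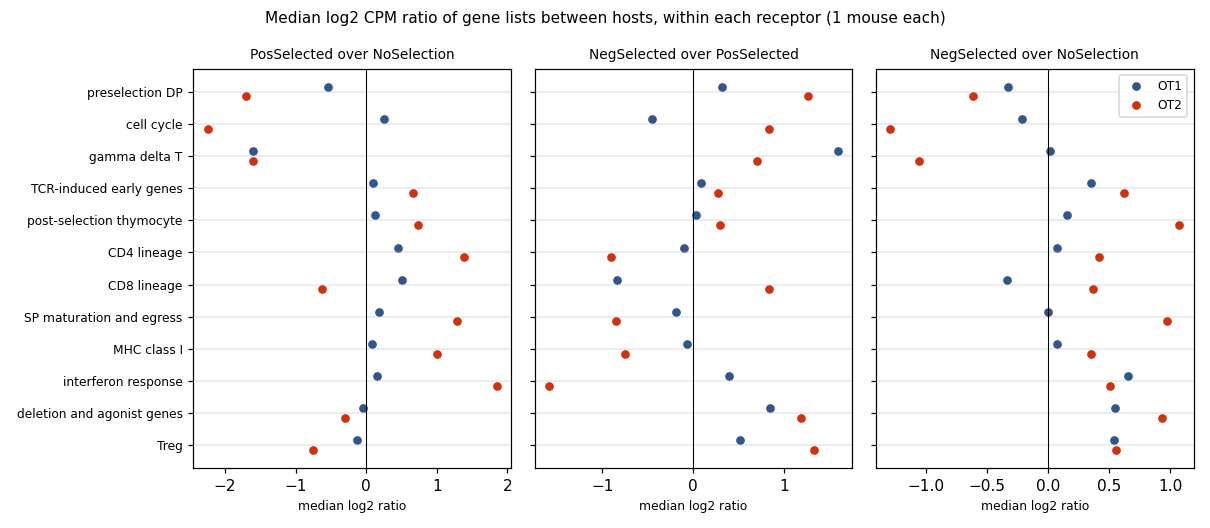
Median log2 ratio of CPM (horizontal axis, 10 CPM added) of 12 gene lists between hosts, OT1 in blue and OT2 in red, 1 mouse per receptor and host, no error. Deletion and agonist genes lie above 0 in both receptors in NegSelected over PosSelected hosts (0.84 and 1.19), and CD8 lineage genes lie on opposite sides (-0.84 and 0.84).

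The comparison of antigen-bearing with non-selecting hosts sets a host with the antigen against a host without the selecting MHC molecule. Receptor signal itself was not measured. TCR-induced early genes rose as a list in NegSelected hosts (11 of 14, median log2 fold change 0.68, camera adjusted p = 1.17e-05, and adjusted p = 0.439 with an estimated correlation). Cd5 measured 266 against 194 CPM in OT1 and 524 against 120 CPM in OT2. Cd69, an early activation marker, measured 119 against 85.7 CPM in OT1 and 136 against 47.5 CPM in OT2. Itm2a measured 325 against 244 CPM in OT1 and 979 against 156 CPM in OT2. The deletion and agonist list rose (13 of 14, median 0.80, camera adjusted p = 5.76e-11, and adjusted p = 0.439 with an estimated correlation).

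No single gene was called of 9092 by edgeR, with 236 at an unadjusted p under 0.05, and none by DESeq2 or limma-voom. In the TCR-induced list 4 genes passed adjusted over the list alone and 0 over all genes, with Nr4a3 (2.30, SE 0.44), Nfkbid (1.05, SE 0.26), Cd5 (1.25, SE 0.34) and Cd69 (0.86, SE 0.27) at the lowest p. In the deletion and agonist list 7 passed adjusted over the list alone, with Xcl1 (6.14, SE 0.76, a fit that depends on the prior count, since OT1 NoSelection had 0 UMIs), Gadd45b (2.92, SE 0.43) and Cd274, which encodes PD-L1 (1.29, SE 0.28), among them, whereas Ikzf2 (0.80, SE 0.37) did not. Post-selection genes rose (9 of 11, median 0.52, adjusted p = 0.000491, and adjusted p = 0.439 with an estimated correlation), with Cd2 (1.29, SE 0.32) and Itm2a (1.46, SE 0.42). Treg genes rose (4 of 5, median 0.79, adjusted p = 0.0126, and adjusted p = 0.439 with an estimated correlation), with Tnfrsf18 (0.79, SE 0.24). Interferon response genes rose (12 of 12, median 0.75, adjusted p = 0.00202, and adjusted p = 0.532 with an estimated correlation), with Ifi27l2a (1.70, SE 0.55). SP maturation and egress genes rose (15 of 17, median 0.30, adjusted p = 0.0043, and adjusted p = 0.532 with an estimated correlation), with Il7r (0.52, SE 0.25), by a median log2 ratio of 0.98 within OT2 and 0.00 within OT1. Preselection DP genes fell (8 of 10, median -0.50, adjusted p = 0.00119, and adjusted p = 0.532 with an estimated correlation), with Endou (-0.77, SE 0.32) and Dntt (-0.46, SE 0.20). Cell cycle genes fell (14 of 14, median -0.82, adjusted p = 8.84e-05, and adjusted p = 0.532 with an estimated correlation), with Mcm5 (-0.99, SE 0.50). Gamma delta T genes fell (4 of 4, median -0.38, adjusted p = 0.0244, and adjusted p = 0.532 with an estimated correlation), with Sox13 (-0.89, SE 0.46). The median log2 ratio was 0.01 in OT1, with 2 of 4 members above 0, and -1.06 in OT2 for gamma delta T genes. It was -0.21 in OT1, with 5 of 14 above 0, and -1.29 in OT2 for cell cycle genes. Without the OT2 NoSelection mouse the direction of the SP maturation (adjusted p = 0.491) and cell cycle lists (adjusted p = 0.366) turned, and without the OT2 NegSelected mouse that of the gamma delta T list (adjusted p = 0.831). Without the OT2 NoSelection mouse the calls of the preselection DP (0.585), post-selection (0.0732), interferon (0.320) and gamma delta T lists (0.491) were lost. Without the OT1 NegSelected mouse those of the preselection DP (0.0826) and interferon lists (0.774) were lost. The share of gamma delta T-like cells was 18.5 points lower in OT2 NegSelected than OT2 NoSelection cells and 40.7% against 42.5% in OT1. CD4 lineage genes (median 0.51, adjusted p = 0.153), CD8 lineage genes (median 0.05, camera direction down, 0.397), CD8aa IEL precursor genes (median -0.19, mean 1.04, 0.245), p53 genes (0.08, 0.397), heat shock genes (-0.21, 0.423), MHC class I genes (0.15, 0.121) and myeloid genes (1.05, 0.0905) were not called.

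Trgv4, at 3.13 against 9.10 CPM in OT1 and 52.6 against 224 CPM in OT2, had an edgeR adjusted p of 0.360, the cell adhesion gene Chl1 (3.34, SE 0.52) 0.376, and Fkbp5 (-1.12, SE 0.22) 1.00. Of the 27 anchor genes, 11 were higher and 4 lower in both receptors. Within OT1, without a test, Ccl5 was 18.2 times as high in NegSelected as in NoSelection cells (359.5 against 19.8 CPM), and within OT2 the histone gene H1f5 measured 27.1 against 323 CPM. No antibody was called by edgeR (5 at an unadjusted p under 0.05, and 0 by limma-trend); GITR had the lowest p (log2 fold change 1.70, SE 0.18, edgeR adjusted p = 0.0876, and a log2 fold change of 0.83 with counts capped at the 99th percentile). Adjusted over the list alone, 4 post-selection genes and 1 Treg gene passed, and 0 interferon, SP maturation, preselection DP, cell cycle and gamma delta T genes. The gene count was 78, 4 and 0 without the OT1 NoSelection, PosSelected and NegSelected mouse and 1, 7 and 0 without the OT2 mouse of the same hosts.

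The comparison of OT2 with OT1 mice, over the 3 hosts, asks how a class II and a class I restricted receptor differ. The NoSelection hosts were not the same, since they lacked B2m for OT1 and MHC class II for OT2. OT2 cells held more RNA of the CD4 lineage: Cd4 measured 141, 286 and 198 CPM in OT2 against 23.6, 38.7 and 22.7 CPM in OT1 (NoSelection, PosSelected, NegSelected; log2 fold change 2.83, SE 0.19, edgeR adjusted p = 0.000232), and Zbtb7b (3.30, SE 0.46) and Cd40lg (2.28, SE 0.36) were also called. The recombinase genes Rag1 (4.35, SE 0.56) and Rag2 (3.98, SE 0.53) were higher in OT2. Cd163l1, a scavenger receptor gene of gamma delta T cells, was lower in OT2 (-4.31, SE 0.30).

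In all, 97 genes of 9092 were called, 61 higher and 36 lower in OT2. Among called genes with a mean of at least 50 CPM and the same direction in 3 of 3 hosts, receptor segments left out, the 8 highest by fold were Xist, the RNA of the inactive X chromosome (7.27, SE 0.32), the ubiquitin ligase gene Rnf43 (7.15, SE 0.23), Erdr1 (5.38, SE 0.29), Rag1, Cd4, Ets2 (2.10, SE 0.19), Nsg2 (1.99, SE 0.20) and the lactate dehydrogenase gene Ldhb (1.68, SE 0.31). The 8 lowest were Cd163l1, Ctla2a (-3.34, SE 0.35), Gem (-2.76, SE 0.43), Camk2b (-2.36, SE 0.22), the histone gene H1f3 (-2.13, SE 0.39), Tmem121 (-1.99, SE 0.30), Atp8b4 (-1.80, SE 0.21) and Crip1 (-1.80, SE 0.24). Their edgeR adjusted p ran from 3.97e-06 (Rnf43) to 0.0472 (H1f3). Xist UMIs stood in 322 of 539 OT2 cells (59.7%) and in 11 of 792 OT1 cells (1.39%), at median depths of 2893 and 5135 RNA UMIs per cell. Runx3, the CD8 lineage regulator, was lower in OT2 in 3 of 3 hosts and missed the threshold (-1.06, SE 0.20, adjusted p = 0.0530).

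By list, CD4 lineage genes rose in OT2 against OT1 (4 of 4, median 2.56, camera adjusted p = 0.000111, and adjusted p = 0.706 with an estimated correlation) with 3 members called over all genes. Preselection DP genes rose (8 of 10, median 1.24, adjusted p = 0.00045, and adjusted p = 0.706 with an estimated correlation) with 4 called. Cell cycle genes fell (14 of 14, median -1.43, adjusted p = 5.95e-07, and adjusted p = 0.706 with an estimated correlation) with none called. Gamma delta T genes fell (4 of 4, median -1.47, adjusted p = 0.000396, and adjusted p = 0.706 with an estimated correlation) with 2 called. Adjusted over the list alone 3, 5, 5 and 3 of the genes of these 4 lists passed. In a check chosen after the results were seen, each other split of the 6 mice gave as many called lists or more. Without the OT1 NoSelection mouse the preselection DP call was lost (adjusted p = 0.109). The CD4-CD8- share was lower in OT2 than OT1 in each host, and cycling cells were 8.82, 10.6 and 7.84% of OT1 and 8.33, 0 and 1.69% of OT2 cells. CD8 lineage genes (median -0.64, adjusted p = 0.0549), deletion and agonist genes (0.34, 0.0635), Treg genes (1.25, 0.0888), CD8aa IEL precursor genes (median 0.29, mean -0.17, 0.213), TCR-induced early genes (0.12, 0.606), post-selection genes (0.03, 0.836), SP maturation genes (0.23, 0.538), interferon genes (median 0.09, camera direction down, 0.538), p53 genes (0.20, 0.471), heat shock genes (-0.26, 0.538), MHC class I genes (0.10, 0.471) and myeloid genes (-0.28, 0.484) were not called. The B cell, NK and ILC, iNKT, erythroid and thymic epithelium lists had fewer than 3 genes past the filter and were not tested.

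No antibody was called between receptors by edgeR (20 at an unadjusted p under 0.05), and 5 were called by limma-trend on centred log ratios. GITR (-1.03, SE 0.15, edgeR adjusted p = 0.0522, and 0.33 with counts capped at the 99th percentile), CD4 (1.88, SE 0.31, adjusted p = 0.0633), CD73 (0.93, SE 0.19, adjusted p = 0.107) and CD62L (-1.43, SE 0.34, adjusted p = 0.144) were not called. With CD4-CD8- cells left out, an alternative chosen after the data were seen, 195 genes were called, and of the 97 genes 77 were tested again, 76 kept their direction and 54 were called again. The count was 465, 181 and 25 without the OT1 NoSelection, PosSelected and NegSelected mouse and 660, 251 and 26 without the OT2 mouse of the same hosts.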

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

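The test of the host of the OT2 NoSelection mouse was written before its result was seen; the tests of hashtags, of the transgenic receptor, of surface gamma delta receptor, of Y-linked genes, of CD4-CD8- cells and of other splits were chosen after the result was seen.

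A set of 11 differences went opposite ways in the receptors; with 1 mouse each, the difference was not tested. From NoSelection to PosSelected hosts, cluster 6 changed by 15.6 points in OT1 and -8.89 points in OT2 (OT2 minus OT1 -24.4 points). With 10 principal components the OT2 shares of this class were 3.70% and 4.33%, so that the OT2 direction turned. CD4+CD8+ cells changed by 5.72 points in OT1 and -27.7 points in OT2 (-33.5 points). On the log2 scale CD8A antibody changed by 1.54 in OT1 and -1.91 in OT2 (-3.45), and CD8B antibody by 1.56 and -2.02 (-3.58). From PosSelected to NegSelected hosts, cluster 6 changed by -12.8 and 7.02 points (19.8 points), cluster 9 by -3.93 and 4.71 points (8.64 points) and CD4-CD8+ cells by -26.2 and 9.11 points (35.3 points). Over the same hosts Cd8a changed by -2.74 and 1.65 on the log2 scale (4.39), Cd8b1 by -2.41 and 1.49 (3.89), CD8A antibody by -1.26 and 1.76 (3.02) and CD8B antibody by -1.38 and 1.69 (3.07).

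Gamma delta T-like cells made up 42.5% of OT1 NoSelection and 21.3% of OT2 NoSelection cells. In the OT2 NoSelection mouse 82.6% of them held a Xist UMI, against 1.39% of OT1 cells, which argues against OT1 cells with a wrong hashtag as the source of most of them. Trbv12-1 went the other way. It measured 1521 CPM in these cells, against 316 CPM in the other cells of that mouse and 2677 CPM in those of the OT1 NoSelection mouse. In the OT1 mice Trbv12-1 CPM of gamma delta T-like cells was at least 1.01 times that of the other cells. The sort took only Vbeta5 positive cells, and a segment count cannot tell the transgenic chain from another chain with that segment. This test therefore cannot decide whether cells without the transgenic receptor passed the sort. In the OT1 NoSelection, PosSelected and NegSelected mice the median TCRGD antibody count of these cells, scaled to the median total, was 12.0, 12.9 and 13.4, against 13.8, 13.2 and 15.5 in the other cells. In the OT2 mice it was 17.3, 14.8 and 16.2 against 15.04, 13.7 and 14.5, so that the order was reversed. The class name rests on RNA, and what gave rise to these cells was not tested.

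The label conflict on the OT2 NoSelection host was weighed with the share of CD4 SP-like and mature SP-like cells, for which a host that kept MHC class II would give a share like that of the wild-type host. No cluster took the mature SP-like name, so only CD4 SP-like cells were counted. Their share was 0.0898 times that of the OT2 PosSelected mouse. This argues against a host that lacked B2m alone.

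Genes that differed between OT2 and OT1 numbered 97, with Xist at the highest fold among those named. Male OT1 donors would leave Xist near absent, as in 11 of 792 OT1 cells, and would bring UMIs of Y-linked genes. The 4 Y-linked genes searched held 0 UMIs in the OT1 mice, but 3 of them held none in any mouse and Kdm5d 2 UMIs in OT2 PosSelected, so no mouse shows that they can be counted. Male OT1 donors therefore cannot be told apart from another cause of the Xist difference. Without CD4-CD8- cells 77 of the 97 genes were tested again, 76 kept their direction and 54 were called (55.7% of the 97). For those 54 the share of these cells is not the whole difference, and for the others it cannot be told apart from a difference within cells. The 10 splits of the 6 mice are too few for a share under 0.05: as many genes were called in 1 of 10 splits (97, highest other 0), as many antibodies in 10 of 10 (0, highest other 2) and as many lists in 10 of 10 (4, highest other 7). The numbers of called antibodies and lists therefore do not set the receptor split apart from other splits.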

How the results depend on the processing

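The tests without CD4-CD8- cells and with capped antibody counts were chosen after the result was seen. Values follow the order PosSelected against NoSelection, NegSelected against PosSelected, NegSelected against NoSelection, and OT2 against OT1, and the cause was not tested. Called genes numbered 1, 0, 0 and 97, with DESeq2 35, 5, 0 and 82, limma-voom 11, 0, 0 and 129, no filter on low counts 280, 98, 54 and 589, no receptor or host term 0, 0, 0 and 45, equal cells 2, 0, 0 and 79, without cells over the 95th percentile 99, 14, 0 and 224, without cycling clusters 30, 0, 0 and 137 and without CD4-CD8- cells 4, 6, 0 and 195. Called antibodies numbered 1, 0, 0 and 0, with limma-trend 1, 0, 0 and 5, with no receptor or host term 0, 0, 0 and 2, and with capped counts 0, 0, 0 and 8. Called lists numbered 9, 9, 9 and 4, and 0 in each comparison with an estimated correlation or fry. With 1 mouse left out, where a lone mouse of a host is assumed to vary like the others, ranges were 0 to 248, 0 to 59, 0 to 78, 25 to 660 genes, 0 to 12, 0 to 12, 0 to 3, 0 to 22 antibodies and 4 to 10, 5 to 11, 3 to 12, 5 to 7 lists. Without the CD4-CD8- cells Trdc had -0.22 (NegSelected against PosSelected), and with capped counts GITR antibody had 0.71 (NegSelected against PosSelected) and 0.33 (OT2 against OT1).

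With 1 mouse left out, camera directions turned for these lists in PosSelected against NoSelection (lowest to highest adjusted p): deletion and agonist genes 0.0543 to 0.759, CD8 lineage 0.00395 to 0.779, Treg 0.405 to 0.859, CD8aa IEL precursor 0.0376 to 0.819, p53 response 0.736 to 0.938, heat shock and dissociation 0.0686 to 0.866, myeloid and dendritic 0.42 to 0.927. With 1 mouse left out, camera directions turned for these lists in NegSelected against PosSelected (lowest to highest adjusted p): post-selection thymocyte 0.152 to 0.957, CD8 lineage 0.00349 to 0.591, interferon response 1.76e-10 to 0.676, p53 response 0.404 to 0.927, cell cycle 4.21e-07 to 0.525, heat shock and dissociation 0.0351 to 0.666, myeloid and dendritic 0.00489 to 0.911. With 1 mouse left out, camera directions turned for these lists in NegSelected against NoSelection (lowest to highest adjusted p): CD8 lineage 0.00019 to 0.821, SP maturation and egress 2.5e-05 to 0.491, p53 response 0.33 to 0.944, cell cycle 3.35e-10 to 0.366, heat shock and dissociation 0.0106 to 0.876, MHC class I 0.0162 to 0.821, myeloid and dendritic 0.0144 to 0.876, gamma delta T 0.0002999 to 0.831. With 1 mouse left out, camera directions turned for these lists in OT2 against OT1 (lowest to highest adjusted p): TCR-induced early genes 0.278 to 0.904, post-selection thymocyte 0.197 to 0.902, CD8 lineage 0.00116 to 0.989, SP maturation and egress 0.0155 to 0.618, interferon response 6.39e-06 to 0.511, heat shock and dissociation 0.0824 to 0.902, MHC class I 0.104 to 0.715, myeloid and dendritic 0.00349 to 0.902. Called lists that kept direction and lost the call with 1 mouse left out had these highest adjusted p: PosSelected against NoSelection TCR-induced early genes 0.21, post-selection thymocyte 0.0947, CD4 lineage 0.121, interferon response 0.11, cell cycle 0.86, MHC class I 0.134; NegSelected against PosSelected preselection DP 0.511, CD4 lineage 0.431, SP maturation and egress 0.532, CD8aa IEL precursor 0.436, MHC class I 0.927, gamma delta T 0.257; NegSelected against NoSelection preselection DP 0.585, post-selection thymocyte 0.0732, interferon response 0.774; OT2 against OT1 preselection DP 0.109. With Leiden resolution 1.5, shares were CD4 SP-like 10.1% (OT1 NoSelection) and 30.1% (OT1 PosSelected) and 13.7% (OT1 NegSelected) and 60.6% (OT2 PosSelected) and 16.4% (OT2 NegSelected), cluster 6 4.63% (OT2 NoSelection), signaled intermediate-like 5.23% (OT1 NoSelection) and 9.57% (OT1 PosSelected) and 9.8% (OT1 NegSelected) and 23.7% (OT2 NegSelected), deletion/agonist-like 1.31% (OT1 NoSelection) and 0.355% (OT1 PosSelected) and 8.33% (OT2 NoSelection) and 0.394% (OT2 PosSelected). The CD4 SP-like name there included clusters of 102 and 64 cells that the naming rule does not compare by name. The deletion/agonist-like name there covered 46 cells, against 131 in the main setting. With 10 principal components, shares were CD4 SP-like 7.84% (OT1 NoSelection) and 23.4% (OT1 PosSelected) and 6.86% (OT1 NegSelected), cluster 6 3.7% (OT2 NoSelection), signaled intermediate-like 1.96% (OT1 NoSelection) and 6.38% (OT1 PosSelected) and 4.41% (OT1 NegSelected) and 2.36% (OT2 PosSelected) and 10.2% (OT2 NegSelected), deletion/agonist-like 1.63% (OT1 NoSelection) and 1.06% (OT1 PosSelected) and 9.26% (OT2 NoSelection) and 0.787% (OT2 PosSelected). Here the CD4 SP-like name included a cluster of 104 cells that the naming rule does not compare by name. The deletion/agonist-like and signaled intermediate-like names here covered 61 and 58 cells, against 131 and 188 in the main setting. With the CD4 and CD8 antibody gate, shares were CD4+CD8- (set against CD4 SP-like) 17.7% (OT1 PosSelected) and 11.8% (OT1 NegSelected) and 75.6% (OT2 PosSelected) and 22.6% (OT2 NegSelected), CD4-CD8+ (against cluster 6) 12.4% (OT1 NoSelection) and 37.9% (OT1 PosSelected) and 11.8% (OT1 NegSelected) and 4.63% (OT2 NoSelection), CD4-CD8- (against gamma delta T-like, a part of these cells) 73.9% (OT1 NoSelection) and 29.8% (OT1 PosSelected) and 67.2% (OT1 NegSelected) and 45.4% (OT2 NoSelection) and 16.9% (OT2 NegSelected), CD4+CD8+ (against preselection DP-like) 8.82% (OT1 NoSelection) and 14.5% (OT1 PosSelected) and 9.31% (OT1 NegSelected) and 13% (OT2 PosSelected) and 48.6% (OT2 NegSelected). With Leiden resolution 0.5, shares were CD4 SP-like 61% (OT2 PosSelected), preselection DP-like 4.9% (OT1 NoSelection) and 6.74% (OT1 PosSelected). With cells over the 95th percentile of UMIs of their mouse left out, shares were gamma delta T-like 2.49% (OT2 PosSelected), deletion/agonist-like 4.56% (OT2 PosSelected). Of 1443 gene folds under an alternative 1149 kept direction and side of the threshold, 252 passed it newly, 41 lost it and 1 turned. Of 100 antibody folds the numbers were 78, 15, 5 and 2, and of 576 list tests 403, 32, 92 and 49. Of 162 shares 112 stayed within their interval. A class name that a cluster setting did not yield has no value there, such as that of cluster 6 at resolution 0.5. In that setting a cluster with the same leading genes (116 cells, 69.0% CD4-CD8+) took the name iNKT-like. The gene folds counted include 91 of the run without the cell filter, which removed no cell and could not differ. No paired analysis was possible by replicate number, because each group has 1 mouse, while the receptor term of the model sets hosts against each other within a receptor.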

Other observations

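The T cell receptor segments and gamma delta genes were viewed after the results were seen, with no test of their own. Xist UMIs stood in 0 of 251 gamma delta T-like cells of OT1 mice. Trbv12-1, the Trbv12 segment with most counts in OT1 mice, measured 2976, 3268 and 3125 CPM in gamma delta T-like cells of the OT1 NoSelection, PosSelected and NegSelected mice. It measured 2677, 2750 and 3083 CPM in their other cells. In OT2 mice it measured 1521, 1365 and 1449 CPM in gamma delta T-like cells and 316, 49.6 and 115 CPM in the other cells. Trbv12-2 measured 1894, 2854 and 837 CPM in gamma delta T-like cells and 675, 797 and 1040 CPM in the other cells of the OT2 mice. Trbv12-1 and Trbv12-2 are near-identical copies, so that the split of reads between them is uncertain.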
